A study of Saccharomyces cerevisiae with 21 samples.

How the data were processed

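The series holds RNA-seq of 21 libraries of yeast in the W303 background, in 7 groups of 3. Per the labels' protocols, cells were grown in YPD to mid-log phase, each replicate being taken on its own day, and harvested on a filter under vacuum; RNA was extracted with acid phenol and chloroform. Libraries were made from poly(A)-selected RNA with a directional (strand-keeping) kit, per the labels' protocols. Groups were taken from the sample titles and genotypes. The tools HISAT2, StringTie and DESeq2 and the builds sacCer3 and R64, names for the same assembly, are given per the submitters' processing notes. Their versions and settings are not given in the sources used here, nor whether the counting used strand.

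The deposited table of levels holds TPM for 6407 genes in the 21 libraries, per the file headers, and no sample column was left unused (0). TPM is scaled to the transcripts of each library by the authors' tools, so the depth of the libraries is unknown and no counting interval can be given. Design choices written before the data were examined allowed for TPM or counts, and the TPM branch was used. The authors' 5 deposited comparison tables have the column names of DESeq2 results, per the file headers: a mean signal over the libraries of the comparison, a log2 fold change of mutant over wild type with its standard error on the log2 scale, a test score, and raw and adjusted p-values. What these deposited p-values were computed from is not stated. The authors' table of snf2del holds only genes with an adjusted p under 0.05. Between 40 and 107 entries of those tables have no counterpart in the table of levels.

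Changes were fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0) on log2 of TPM plus a pseudocount of 1, for genes with at least 1 TPM in at least 3 libraries of the fit, with trended and robust moderation. The SWI3 family (9 libraries) and the SNF2 family (12 libraries) were fitted apart, and comparisons across families in all 21 libraries, giving 13 comparisons. A call is a Benjamini-Hochberg adjusted p under 0.05 from limma over the genes tested in the comparison; calls with a log2 change of at least 1 in size were also counted. Every adjusted p of a gene is limma's, two-sided, over n = 3 libraries per group.

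Before the data were examined 27 gene lists were fixed and tested, of which 1 is not reported here, and the report does not give every list for every comparison. The others are Swi/Snf subunits, genes known to need Swi/Snf, genes known for interference, phosphate, hexose transport, glucose-repressed, respiratory (tricarboxylic acid cycle and respiratory chain), glycolytic, ribosomal protein, ribosome biogenesis, histone, Gcn4 amino acid, purine, iron, zinc, inositol and phospholipid, ergosterol, stress, hypoxic, flocculin and adhesin, a-specific, alpha-specific, haploid and pheromone, meiotic, proteasome and strain marker genes. Lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the 27 lists of a comparison, and again with an estimated correlation and with limma's fry. Adjusted p of lists are from camera unless an estimated correlation is named. Genes named in the text were chosen by a rule fixed before the data were examined. It took the targeted subunits, the 10 largest rises and 10 largest falls per mutant (5 for other comparisons) among called genes with a log2 change of at least 1 in size, a mean of at least 10 TPM in the higher group and no overlap of replicates, up to 4 members per list with the smallest p, and INO1, SUC2, SER3, HO, PHO84, PHO5, FLO11, HTA1 and HTB1. SIR4, SRG1, SER33 and the genes of the chromosome IV stretch outside this rule were chosen after their values were seen.

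Overlaps of calls between comparisons that share control libraries were set beside 50 simulations of unchanged groups against the same controls. Gene positions are from the R64 annotation, to which 5951 names matched and 456 did not; genes within 20 kb of a chromosome end were called end genes. Similar copies of genes were found with BLAST 2.17.0. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. The alternatives tried were other pseudocounts, no filter on low levels, median-ratio and quantile scaling, plain moderation, other sets of libraries in the fit, a replicate block, and each library left out in turn.

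The fit was tested on simulated data made from the levels and spreads of the real genes, with 50 genes changed at each log2 size. The changed genes were drawn without those of the lowest levels, and the simulated spread was normal and independent between genes and libraries. The shares and false calls may thus be too favourable for genes of low level and for real libraries. For swi3-E815X against SWI3 (6393 genes), 22% of changes of 0.25, 84% of changes of 0.5, 98% of changes of 1 and 100% of changes of 2 were called, with 6 calls among 6163 unchanged genes. For snf2-W935R against SNF2 (6392 genes), the shares were 26%, 84%, 98% and 98%, with 8 calls among 6162 unchanged genes. For the difference between the deletion effects (6400 genes) they were 10%, 46%, 96% and 100%, with 6 calls among 6170 unchanged genes.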

Results

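Messenger RNA was measured by sequencing in 21 libraries of the budding yeast Saccharomyces cerevisiae, strain background W303, grown in rich glucose medium (YPD) to mid-log phase. The series concerns Swi/Snf, a complex that moves nucleosomes with the energy of ATP, and its part in transcriptional interference, in which transcription across one region lowers the use of a promoter within it. Per the labels, the strains lack the chromosomal copy of SWI3 (a structural subunit) or of SNF2 (the ATPase) and carry a wild-type copy, a mutant copy or no copy of that gene, each written with the marker LEU2. There were 7 groups of 3 libraries: SWI3, swi3-E815X and swi3del in one family, and SNF2, snf2-W935R, snf2-Q928K and snf2del in the other. The table of levels holds 6407 genes in TPM, a level scaled to the transcripts of each library, whose sums per library lay between 960811 and 1000396. TPM keeps no record of the number of reads, so the depth of the libraries is unknown. Between 6311 and 6393 genes reached 1 TPM in a library, and the correlation of replicates across genes lay between 0.987 and 0.995. Levels are given as mean ± SD over n = 3 libraries, and changes as log2 fold changes of TPM + 1 with their standard error (SE), which understate the change of genes with few transcripts.

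The targeted subunit was examined first. SWI3 (YJL176C, chromosome X 92053 to 94530 in R64) stood at 37.1 ± 1.38 TPM in the SWI3 wild type and 35.5 ± 0.967 in swi3-E815X, and at 0.127 ± 0.0601 in swi3del. In the other family it stood at 44.6 ± 0.781 in the SNF2 wild type, 45.4 ± 2.04 in snf2-W935R, 42.2 ± 2.22 in snf2-Q928K and 33.4 ± 1.52 in snf2del. The level of SNF2 itself is not analysed here, so its deletion was not checked on its own RNA. The marker LEU2 (YCL018W) had 136 ± 1.84 TPM in swi3del and 151 ± 19.9 in snf2del, against 0.226 ± 0.0886 in SWI3, 0.252 ± 0.104 in swi3-E815X, 0.336 ± 0.187 in SNF2, 0.293 ± 0.102 in snf2-W935R and 0.474 ± 0.0852 in snf2-Q928K. LEU2 RNA was thus near 0 in the 5 groups with a copy of SWI3 or SNF2, whose labels name LEU2, and high in both deletions. The design choices place the wild-type copies at the LEU2 locus, so a copy in place of LEU2 may account for this. That was not tested. Because LEU2 is a marker of the strains, its changes in the later comparisons cannot be told apart from a difference between constructs.

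**Figure D1:**
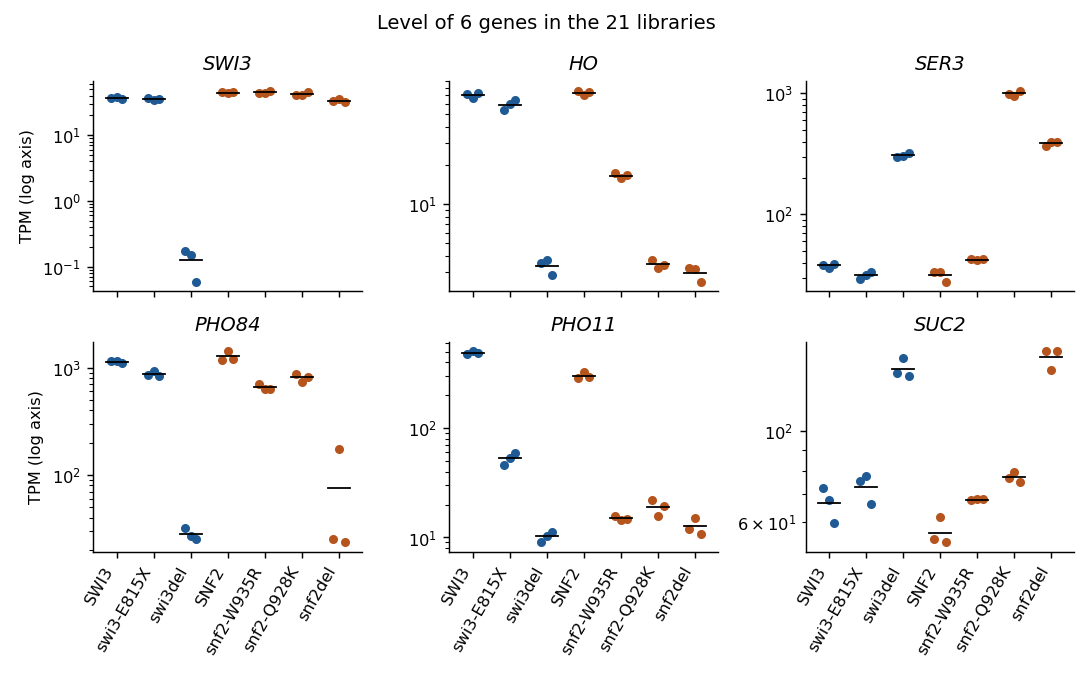
Level of 6 genes in TPM (log axis) in each of the 21 libraries, with the SWI3 family in blue and the SNF2 family in orange; each point is a library and each line the mean of its group. SWI3 is near 0 only in swi3del among these groups, HO is lowest in both deletions and snf2-Q928K, SER3 is highest in snf2-Q928K at a mean of 998 TPM, and PHO84 of snf2del has 1 library apart at 175 TPM.

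Loss of Swi3 lowered HO and the genes of phosphate uptake and of ribosome production, and raised those of respiration and stress and those repressed by glucose. These lists passed with the preset correlation and not with an estimated one (adjusted p between 0.0822 and 0.424), and some members went the other way. HO, the endonuclease of mating-type switching (YDL227C, chromosome IV 46271 to 48031), fell from 70.1 ± 3.17 TPM in SWI3 to 3.35 ± 0.442 in swi3del. PHO84, the high-affinity phosphate transporter (YML123C, chromosome XIII 24037 to 25800), fell from 1135 ± 32.8 to 28.0 ± 3.6, and YHB1, the flavohaemoglobin that detoxifies nitric oxide (YGR234W, chromosome VII 959904 to 961103), from 1653 ± 25.6 to 46.2 ± 3.75. SER3, the first enzyme of serine synthesis (YER081W, chromosome V 322686 to 324095), rose from 37.9 ± 1.35 to 308 ± 13.4 TPM, a log2 change of 2.99 ± 0.07 (limma adjusted p = 3.12e-11). PIR3, a cell wall protein, rose from 8.45 ± 1.33 to 482 ± 45.5, and GUT2, the mitochondrial glycerol-3-phosphate dehydrogenase, from 14.2 ± 0.5 to 297 ± 20.9.

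Among the other genes with the largest changes in swi3del, LEU2 (the strain marker), RTS3, DSF1, ECM13, ICY2, the mitochondrial ADP/ATP carrier AAC1, TMA10 and the autophagy gene ATG8 rose by log2 changes between 3.87 and 6.81. PHO12 and PHO11 (secreted acid phosphatases whose near-identical sequences may share reads), SPL2, PHM6, INA1 and MRH1 fell, with log2 changes between -5.49 and -3.34. Of the genes chosen beforehand for their known dependence on Swi/Snf or on interference, INO1 (log2 change 1.45 ± 0.13), SUC2 (1.08 ± 0.09) and FLO11 (1.28 ± 0.12) were higher in the deletion. PHO5 was lower (-3.18 ± 0.08), as were the histone genes HTA1 (-1.14 ± 0.06) and HTB1 (-0.71 ± 0.09). Each of these passed limma's test, and in each the 3 libraries of one group lay apart from the 3 of the other. In the authors' deposited table INO1 was not called in swi3del (adjusted p = 0.0503). Cells were grown only in rich glucose medium, so activation of these genes in other media was not measured.

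By list, 14 of 16 phosphate genes fell and 2 rose, with a median 2.51 below the median of all genes on the log2 scale (adjusted p = 2.14e-10 with the preset correlation, 0.0822 with an estimated correlation). Of 137 ribosomal protein genes 127 fell, among them RPL16A (-1.09 ± 0.06) and RPL27B (-1.15 ± 0.07), and of 58 ribosome biogenesis genes 57 fell, among them DBP2 (-2.12 ± 0.08) and NSR1 (-1.85 ± 0.07). Histone genes fell in 7 of 10 cases. Of 44 genes of the tricarboxylic acid cycle and respiratory chain 42 rose, with SDH4 at 2.32 ± 0.09 and CIT1 at 1.97 ± 0.08. Of 29 stress genes 27 rose (XBP1 3.15 ± 0.11, HSP42 2.77 ± 0.13), of 23 glucose-repressed genes 19 (ALD4 2.87 ± 0.08, MDH2 2.71 ± 0.09), and all 7 measured flocculin and adhesin genes, of which FLO1 and FLO5 are similar in sequence. Glycolytic genes went both ways: 10 of 19 fell, with ENO2 at -2.64 ± 0.07 and GPM1 at -2.25 ± 0.07, and 6 rose, with GLK1 at 2.84 ± 0.09. All of these lists passed camera with the preset correlation, at adjusted p = 0.0232 for glycolysis and at 0.0185 or less for the others. With an estimated correlation none did, the smallest adjusted p being the 0.0822 of the phosphate list.

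Counts adjusted over the list alone differed from these by at most 1 gene: 128 falls of ribosomal protein genes and 43 rises of respiratory genes. Amino acid synthesis genes under Gcn4 rose in 29 of 41 cases and fell in 9 (ARG4 2.44 ± 0.07, SNZ1 3.68 ± 0.11; adjusted p = 0.0232, and 0.683 with an estimated correlation). The 11 genes known from earlier work to need Swi/Snf split into 6 that fell and 4 that rose (adjusted p = 0.0241, and 0.241 with an estimated correlation). The remaining lists did not pass in swi3del. They were the genes known for interference (9 rose and 5 fell of 16), hexose transport (9 and 3 of 15), iron (13 and 4 of 19), zinc (5 and 3 of 8), inositol and phospholipid synthesis (9 and 3 of 14), ergosterol (14 and 4 of 23), purine (6 and 10 of 17), hypoxic genes (6 and 6 of 13), meiosis (16 and 1 of 24), proteasome (16 and 0 of 32), a-specific (3 and 3 of 7), alpha-specific (1 and 0 of 3), haploid and pheromone genes (4 and 5 of 20), Swi/Snf subunits (5 and 2 of 11) and strain markers (5 and 0 of 6). Median-ratio scaling changed the rises and falls to 3 and 5 in the subunit list, 6 and 3 in the proteasome list, 3 and 10 in the haploid list and 12 and 8 in the ergosterol list.

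In all, 3029 of 6395 genes were higher and 1554 lower in swi3del, 1122 and 324 of them by 2-fold or more. The median gene was 0.23 higher on the log2 scale. After scaling the libraries by the median ratio of all genes the split became 2289 higher and 2280 lower (788 and 573 by 2-fold or more), so the balance of rises and falls depends on the scaling, and list medians are given relative to the median of all genes.

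The swi3-E815X allele of SWI3 lowered the phosphate genes, and its largest rises include genes of arginine and sulfur metabolism, for which no list was tested. PHO5, a secreted acid phosphatase (YBR093C, chromosome II 429548 to 430951), fell from 211 ± 9.37 to 31.0 ± 2.30 TPM (log2 change -2.73 ± 0.08, adjusted p = 5.46e-09). PHO11 and PHO12 fell by more (-3.19 ± 0.10 and -3.17 ± 0.11), and the transporter PHO89 and the regulator SPL2 by -2.22 ± 0.12 and -1.97 ± 0.17 on that scale. PHO84 moved little, from 1135 ± 32.8 to 878 ± 50.7 (-0.37 ± 0.09, adjusted p = 0.0168), and this call was lost without SWI3 replicate 1 (-0.36) or 2 (-0.36) and without swi3-E815X replicate 1 (-0.36) or 3 (-0.34). The other largest falls were in YRO2, BSC1, YGP1, PRM7 and TIR1, at log2 changes between -2.76 and -1.99. Of the arginine genes, ARG3 rose by 2.12 ± 0.15, ARG1 by 1.84 ± 0.09 and ARG5,6 by 1.55 ± 0.07. Of the genes of sulfate uptake and methionine synthesis, the largest rises hold MET28 at 2.13 ± 0.21, MET3 at 1.80 ± 0.09, STR3 at 1.58 ± 0.10, SUL2 at 1.53 ± 0.14 and MET14 at 1.41 ± 0.08; SPO24 and ICY2 complete the 10 largest rises.

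HO stood at 59.2 ± 5.42 TPM in swi3-E815X (-0.24 ± 0.10, adjusted p = 0.178), SUC2 at 73.0 ± 6.01 (0.13 ± 0.09, 0.440) and FLO11 at 10.8 ± 1.31 (0.06 ± 0.12, 0.818). HTA1 and HTB1 gave 0.01 ± 0.06 (adjusted p = 0.928) and 0.08 ± 0.09 (0.647). SER3 and INO1 were slightly lower, at -0.27 ± 0.07 (0.0412) and -0.52 ± 0.13 (0.0312), and both calls were fragile. That of INO1 was lost without SWI3 replicate 1 (-0.46) or 3 (-0.53) and without swi3-E815X replicate 1 (-0.52) or 2 (-0.45), and that of SER3 in each fit without 1 library except that without swi3-E815X replicate 3, at values between -0.30 and -0.22. Of the 16 phosphate genes 15 fell and none rose, with a median 1.01 below that of all genes. This was the single list of this comparison to pass with an estimated correlation (adjusted p = 0.00998; 4.18e-22 with the preset one). Gcn4 genes rose in 17 of 41 cases and fell in 4 (adjusted p = 3.39e-08; 0.536 with an estimated correlation). Stress genes fell in 5 of 29, led by YGP1 at -2.58 ± 0.09 (adjusted p = 0.0025; 0.536 with an estimated correlation). Of 137 ribosomal protein genes none passed in limma, and the list had an adjusted p = 0.866. A further 10 lists passed with the preset correlation and not with an estimated one, with few members called: among them 7 of 19 iron genes, 4 of 13 hypoxic genes, 3 of 20 haploid genes and 2 of 58 ribosome biogenesis genes fell, and 5 of 23 ergosterol genes and 2 of 44 respiratory genes rose. Adjusted over the list alone, the falls were 9 for iron, 6 for hypoxic and 0 for ribosome biogenesis genes, and ergosterol genes had 8 rises and 2 falls. With a replicate block the hypoxic list (adjusted p = 0.0626) and the zinc list (0.0627) no longer passed. The interference list did not pass, with 2 rises and 4 falls of 16 (0.582).

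In total 196 genes were higher and 369 lower in swi3-E815X, 29 and 90 by 2-fold or more; median-ratio scaling gave 230 and 338, with 31 and 86 by 2-fold. Set against swi3del directly, the allele had 1335 genes higher and 3071 lower (2180 and 2128 after median-ratio scaling). Besides SWI3 itself, the genes most above the deletion were YHB1 (5.03 ± 0.08), PHO84 (4.93 ± 0.09), INA1 (4.09 ± 0.07) and HO (3.79 ± 0.10). Those most below it were LEU2, PIR3 (-5.92 ± 0.25), DSF1, RTS3 and GUT2 (-3.91 ± 0.08). Ribosomal protein genes were higher in the allele in 131 of 137 cases and stress genes lower in 28 of 29 (adjusted p = 3.20e-37 and 5.77e-07; 0.168 for both with an estimated correlation).

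**Figure D2:**
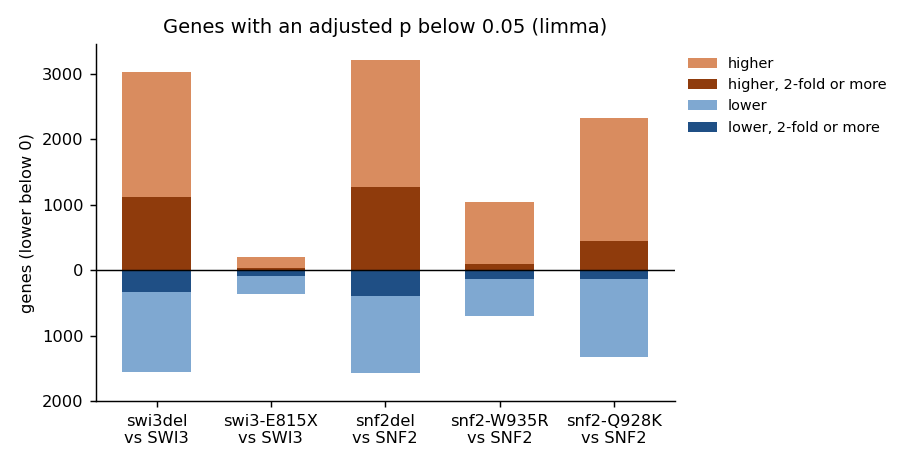
Number of genes with an adjusted p below 0.05 (limma) in each mutant against its own wild type, with higher genes above 0 and lower genes below; dark parts are changes of 2-fold or more. The deletions have 4583 and 4786 such genes, snf2-Q928K 3646, snf2-W935R 1739 and swi3-E815X 565.

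The wild types themselves were compared before the SNF2 family, since each serves as a control. Genes in one stretch of chromosome IV were higher in the SNF2 wild type than in the SWI3 wild type, at a median TPM ratio of 1.91. The stretch runs from GCD6 to EXG2, 884727 to 979209 in R64, between 2 pairs of Ty element genes, and holds 48 measured genes. Their median log2 difference was 0.92, and 44 were called. COX20 stood at 41.3 ± 1.53 TPM against 17.1 ± 2.34, the checkpoint gene RAD9 at 47.4 ± 1.62 against 21.4 ± 2.35, and SWM1, YAP6 and PEX5 were higher by log2 differences of 1.29 ± 0.10, 1.16 ± 0.12 and 1.16 ± 0.10. The medians over the stretch in the other groups against the SWI3 wild type lay between -0.04 in swi3-E815X and 0.17 in snf2del. Genes within 20 kb of a chromosome end were lower in the SNF2 wild type, 76 of 227 by the test with 3 higher, at a median of -0.26. RDS1, ADH7 and AAD3, neighbours between 309070 and 314981 on chromosome III, stood at 0.548 ± 0.249, 0.585 ± 0.137 and 3.81 ± 0.301 TPM in SNF2 against 16.2 ± 1.76, 15.9 ± 0.523 and 26.8 ± 0.891 in SWI3. COS8, whose reads may be shared with similar subtelomeric genes, was lower by -2.52 ± 0.15, and COS10, with 0 similar copies found as for RDS1 and ADH7, by -1.86 ± 0.15. In all 90 genes were higher and 164 lower in SNF2, and 21 and 40 without the stretch and the ends, an alternative chosen after seeing the data. Without SNF2 replicate 1 the lower genes numbered 95, and without SWI3 replicate 1 they numbered 105. Iron genes were higher in SNF2 in 6 of 19 cases (adjusted p = 2.71e-08; 0.591 with an estimated correlation). Another 7 lists passed with the preset correlation alone, with at most 7 members called in each; the interference list was one of them, with 3 of 16 genes lower (0.0341; 0.591 with an estimated correlation).

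**Figure D3:**
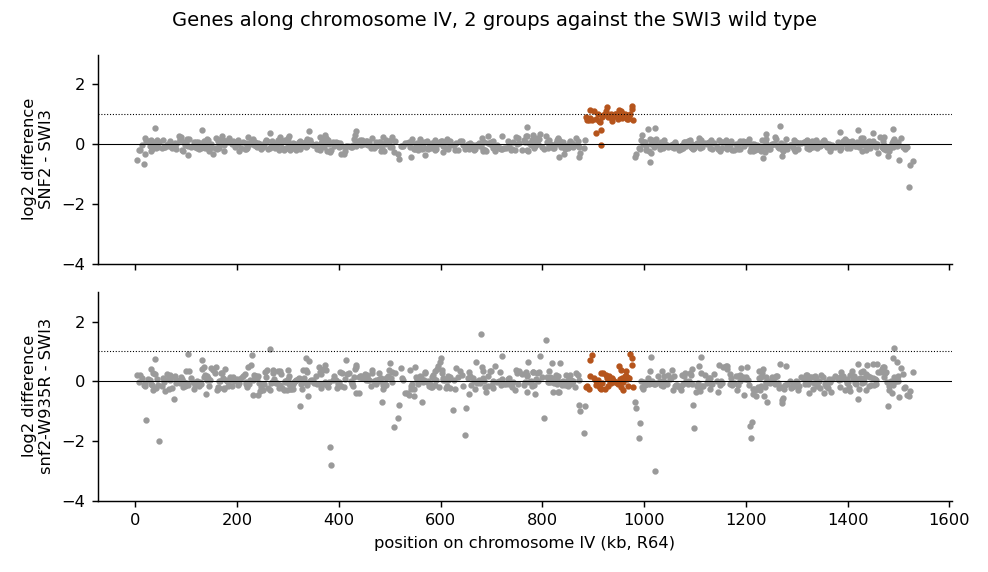
Log2 difference of each gene of chromosome IV against the SWI3 wild type, by position in kb of R64: the SNF2 wild type above and snf2-W935R below. Orange points are the 48 genes of the stretch, grey points all other genes, and the dotted line marks a log2 difference of 1; the stretch has a median of 0.92 in the SNF2 wild type and 0.04 in snf2-W935R.

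In snf2del HO fell from 73.3 ± 3.29 to 2.95 ± 0.383 TPM, YHB1 from 1487 ± 84.3 to 38.6 ± 4.77 and INA1 from 426 ± 31.3 to 22.7 ± 2.98. SER3 rose from 31.6 ± 3.31 to 386 ± 14.3 (log2 change 3.57 ± 0.07, adjusted p = 4.68e-14), PIR3 from 6.98 ± 0.662 to 510 ± 228 and GUT2 from 16.4 ± 2.25 to 353 ± 11.0. PHO84 fell from 1271 ± 133 to 74.8 ± 87.0 TPM (-4.70 ± 0.65, adjusted p = 1.66e-04), with snf2del replicate 2 at 175 TPM and the other 2 libraries at 25.5 and 23.6. The phosphate genes SPL2, PHM6, PHO12, PHO11 and PHO89 fell by log2 changes between -5.14 and -3.56. RPL22A is also among the 10 largest falls, but its level varied widely within groups, at 123 ± 80.6 TPM in SNF2. Its call was lost with the SWI3 wild type as the control, at a log2 change of -2.26. LEU2 (the strain marker), AAC1, DSF1 and RTS3 rose by log2 changes between 4.31 and 6.83. The rises of ADH7, IMD2 and COS8, all near chromosome ends, and of IMD1, similar in sequence to IMD2, were taken against low levels in the SNF2 wild type. Against the SWI3 wild type COS8 went from 69.0 ± 2.12 to 207 ± 18.5.

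INO1 (1.90 ± 0.14), SUC2 (1.42 ± 0.07) and FLO11 (1.44 ± 0.10) were higher in snf2del and PHO5 lower (-2.95 ± 0.12). HTA1 and HTB1 were each lower by -1.24 on the log2 scale, with SE 0.07 and 0.09; both lie in the chromosome IV stretch, where HTA1 stood at 778 ± 47.9 TPM in SNF2 and 788 ± 16.9 in SWI3, and HTB1 at 1157 ± 104 and 832 ± 22.3. Phosphate genes fell in 14 of 16 cases (median 2.65 below all genes), ribosomal protein genes in 130 of 137, ribosome biogenesis genes in 56 of 58 and histone genes in 8 of 10. Respiratory genes rose in 42 of 44 cases (LSC2 1.74 ± 0.07), stress genes in 27 of 29 (HSP26 3.86 ± 0.17), glucose-repressed genes in 20 of 23 (JEN1 2.94 ± 0.13), and all 7 flocculin and adhesin genes rose. Gcn4 genes rose in 30 of 41 cases (8 fell), meiotic genes in 20 of 24 and proteasome genes in 26 of 32, the last at a median of only 0.03 above all genes and with 9 rises and 5 falls after median-ratio scaling. These 11 lists passed camera (adjusted p = 0.036 or less) and the glycolytic list (0.0909) and the interference list (11 rises and 5 falls of 16, 0.678) did not. With an estimated correlation none passed, the smallest adjusted p of these being 0.337. With the SWI3 wild type as the control, an alternative chosen after seeing the data, the Gcn4, meiotic and proteasome lists no longer passed (adjusted p = 0.0647, 0.0722 and 0.0987) and the glycolytic list did (0.026).

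In total 3212 of 6398 genes were higher and 1574 lower in snf2del, 1266 and 399 by 2-fold or more. Of the 1266 genes 153 lie near chromosome ends, and of the 399 genes 19 in the chromosome IV stretch. Median-ratio scaling gave 2429 and 2414, with 893 and 649 by 2-fold or more, and the median gene was 0.26 higher on the log2 scale. Against the SWI3 wild type end genes were higher in both deletions, at medians of 0.83 in snf2del and 0.82 in swi3del. In swi3del 169 of 225 end genes were called higher and 18 lower. The rise of end genes in snf2del thus does not rest on the low SNF2 wild type alone. The fold changes of both deletions correlated across genes with Pearson's r = 0.943, genes not being independent replicates. Of the genes tested in both, 2830 were higher in each and 1355 lower in each, against 1521 and 382 for independent lists; 9 had opposite calls.

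The snf2-W935R allele combined strong falls of phosphate genes with rises of respiratory genes and of ARG3, ARG1 and ARG5,6; arginine genes were not tested as a list. The phosphate and respiratory lists did not pass with an estimated correlation (adjusted p = 0.141 and 0.288). PHO89 fell from 167 ± 10.8 to 6.35 ± 1.70 TPM, below its 13.6 ± 3.93 in snf2del, and SPL2 from 97.0 ± 10.9 to 3.09 ± 0.278. PHO5 fell to 21.6 ± 2.46 and PHO11 and PHO12 by -4.24 ± 0.12 and -4.32 ± 0.11, while PHO84 stood at 657 ± 45.9 against 1271 ± 133 TPM (-0.95 ± 0.65, adjusted p = 0.332 with all 4 groups in the fit, and a call with the same log2 change when only these 2 groups were fitted). HO fell to 16.6 ± 0.758 TPM (-2.08 ± 0.11, adjusted p = 3.31e-09). ARG3 rose from 22.8 ± 10.6 to 179 ± 4.48, ARG1 from 59.0 ± 13.3 to 424 ± 14.2 and ARG5,6 by 2.37 ± 0.09; SPO24 and PHO87 were also among the largest rises. PHM6, BSC1, VTC3, the peptide transporter PTR2 (-2.18 ± 0.11) and the iron-regulated TIS11 (-2.15 ± 0.25) completed the largest falls. RDS1, ADH7, AAD3, COS8 and IMD2 rank among the 10 largest rises against SNF2, yet all lie near chromosome ends. Against the SWI3 wild type RDS1, ADH7, AAD3 and COS8 differed by 0.07, -0.01, 0.06 and -0.01 on the log2 scale, with no call.

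SER3 stood at 42.2 ± 0.470 TPM in snf2-W935R against 31.6 ± 3.31 (0.41 ± 0.07, adjusted p = 8.19e-04), a call lost with the SWI3 wild type as the control (0.15). SUC2 gave 0.27 ± 0.07 (0.0106; no call against SWI3, at 0.03, or without SNF2 replicate 3, at 0.23), FLO11 0.43 ± 0.10 (0.00589) and INO1 -0.01 ± 0.14 (0.948). HTA1 gave -0.24 ± 0.07 (0.0264, lost without SNF2 replicate 1 or 2, at -0.21 and -0.22, and without each snf2-W935R library, at -0.26, -0.24 and -0.21) and HTB1 -0.19 ± 0.09 (0.129), both genes of the chromosome IV stretch. Over that stretch 43 of 48 genes were called lower in snf2-W935R, at a median of -0.90. Phosphate genes fell in 14 of 16 cases, and iron genes in 12 of 19 (ENB1 -2.12 ± 0.09, ARN1 -1.5 ± 0.09). Iron genes were high in the SNF2 wild type, and with the SWI3 wild type as the control 8 of them fell, the list passing at an adjusted p = 0.0157. Ribosome biogenesis genes fell in 28 of 58 cases (34 adjusted over the list alone), at a median 0.27 below all genes. Respiratory genes rose in 41 of 44 cases (IDH1 0.93 ± 0.07, ACO1 1.01 ± 0.10), Gcn4 genes in 31 of 41 (2 fell), glycolytic genes in 12 of 19 (GLK1 1.33 ± 0.10) and ergosterol genes in 12 of 23. These 7 lists passed camera at adjusted p = 5.76e-04 or less, and none with an estimated correlation, where the Gcn4 list had the smallest of theirs (0.138). Stress genes rose in 12 of 29 cases, while YGP1 of that list had a log2 change of -1.62 ± 0.11 (adjusted p = 0.00475; 0.406 with an estimated correlation). Purine genes fell in 10 of 17 cases, and ribosomal protein genes in 13 of 137, of which none passed when adjusted over the list alone (adjusted p = 3.24e-04 for both lists; 0.362 and 0.542 with an estimated correlation). With the SWI3 wild type as the control 37 ribosomal protein genes fell and 3 rose. Glucose-repressed genes rose in 7 of 23 cases, and their list no longer passed with the SWI3 wild type as the control (adjusted p = 0.0311 and 0.838), or with an estimated correlation (0.456). The genes known to need Swi/Snf (2 rises and 4 falls of 11), zinc (0 and 3 of 8), hypoxic (3 and 6 of 13), a-specific (0 and 2 of 7) and haploid genes (0 and 5 of 20) passed at adjusted p between 0.0158 and 0.0405, and none of them with an estimated correlation. The interference list did not pass (8 rises and 3 falls of 16, 0.187).

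In total 1041 genes were higher and 698 lower in snf2-W935R (988 and 915 after median-ratio scaling), 95 and 132 by 2-fold or more (92 and 136). Of the 95 genes 30 lie near chromosome ends, where the SNF2 wild type is low, and of the 132 genes 15 lie in the chromosome IV stretch, where it is high. With the SWI3 wild type as the control the counts were 1056 and 907. Against snf2del the allele had 1500 genes higher and 3105 lower (2382 and 2303 after median-ratio scaling), led by YHB1 (5.13 ± 0.08), INA1, PHO84, DSE4 and LYS20 above and, after LEU2, PIR3, RDN5-2, RDN5-1 and DSF1 below. RDN5-1 and RDN5-2 are 5S ribosomal RNA genes of the repeated ribosomal DNA, uncertain in libraries selected for poly(A), at 36.2 ± 3.11 and 21.6 ± 1.08 TPM in snf2-W935R, 136 ± 15.1 and 79.7 ± 12.0 in SNF2 and 867 ± 271 and 532 ± 164 in snf2del.

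In snf2-Q928K the largest rise was that of SER3, from 31.6 ± 3.31 to 998 ± 54.2 TPM (log2 change 4.94 ± 0.07, adjusted p = 2.90e-15), above the 386 ± 14.3 of snf2del. SRG1, the noncoding RNA transcribed across the SER3 promoter (chromosome V 322212 to 322762, same strand), was at 43.6 ± 4.60 TPM against 32.9 ± 1.98; its annotation overlaps that of SER3 by 77 bases, so reads of one could be given to the other. HO fell to 3.44 ± 0.241 TPM and YHB1 to 132 ± 8.94 from 1487 ± 84.3, near and above their levels in the deletion. PTR2 fell from 216 ± 22.5 to 17.2 ± 1.38. SPL2, PHM6, PHO12, PHO11, PHO89, PHO5 and VTC3 fell by log2 changes between -5.12 and -2.43, while PHO84 stood at 814 ± 68.7 (-0.64 ± 0.65, adjusted p = 0.431, and a call with only these 2 groups fitted). ARG3 and ARG5,6 rose by 3.29 ± 0.31 and 3.08 ± 0.09, SOL4 by 3.15 ± 0.24 and SPO24 by 2.82 ± 0.10. The carbonic anhydrase NCE103 rose by 3.02 ± 0.77, with a wide spread of 1161 ± 673 TPM. ADH7, RDS1, COS8 and AAD3 are among the largest rises too. Against the SWI3 wild type RDS1 was not called (0.15). ADH7, COS8 and AAD3 are also low in the SNF2 wild type, so their rises against it are larger than against the SWI3 wild type.

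INO1 (1.5 ± 0.14), FLO11 (1.08 ± 0.10) and SUC2 (0.45 ± 0.07) were higher in snf2-Q928K, and HTA1 (-0.55 ± 0.07) and HTB1 (-0.54 ± 0.09) lower. The authors' deposited table did not call INO1 there (adjusted p = 0.0617). HTB1 was no longer called against the SWI3 wild type (-0.07), and over the chromosome IV stretch 43 of 48 genes were lower, at a median of -0.82. Phosphate genes fell in 13 of 16 cases, ribosomal protein genes in 112 of 137 (median 0.52 below all genes), ribosome biogenesis genes in 45 of 58 and histone genes in 5 of 10. Stress genes rose in 26 of 29 cases (HSP42 2.0 ± 0.10), glucose-repressed genes in 19 of 23 (GUT2 2.47 ± 0.11), respiratory genes in 37 of 44, Gcn4 genes in 33 of 41 (5 fell; ARG4 2.07 ± 0.07), ergosterol genes in 18 of 23 (ERG4 1.25 ± 0.07) and all 7 flocculin and adhesin genes. These 10 lists passed camera, at adjusted p = 0.0359 for histones and 0.0143 or less for the others, and none with an estimated correlation (smallest adjusted p = 0.302). The histone list did not pass against the SWI3 wild type (0.086). The interference list did not pass (8 rises and 3 falls of 16, 0.392). Counts adjusted over the list alone changed by at most 1 gene: 113 falls of ribosomal protein and 46 of ribosome biogenesis genes.

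In total 2320 genes were higher and 1326 lower in snf2-Q928K (1865 and 1928 after median-ratio scaling), 451 and 137 by 2-fold or more (376 and 178). Of the 451 genes 94 lie near chromosome ends, and of the 137 genes 15 in the chromosome IV stretch. Against snf2del it had 1424 genes higher and 2592 lower (2102 and 1897 after median-ratio scaling). RPL22A, PHO84 (4.06 ± 0.65), INA1 (3.83 ± 0.09), DSE4 (2.07 ± 0.07) and MRH1 (2.02 ± 0.12) led the genes above the deletion, and LEU2, PIR3 (-4.61 ± 0.30), ECM13, DSF1 and RDN5-2 those below. Against snf2-W935R it had 1918 genes higher and 900 lower (1468 and 1396 after median-ratio scaling). SER3 (4.53 ± 0.07), BSC1 (2.40 ± 0.14), IZH4, HPF1 and SNZ1 (2.06 ± 0.16) were most above snf2-W935R, and YHB1 (-3.38 ± 0.08), HO (-1.99 ± 0.11), ZEO1, CWP1 and HXT4 most below. Ribosomal protein genes were lower than in snf2-W935R in 94 of 137 cases and stress genes higher in 23 of 29 (adjusted p = 8.93e-26 and 1.76e-07; 0.338 for both with an estimated correlation).

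**Figure D4:**
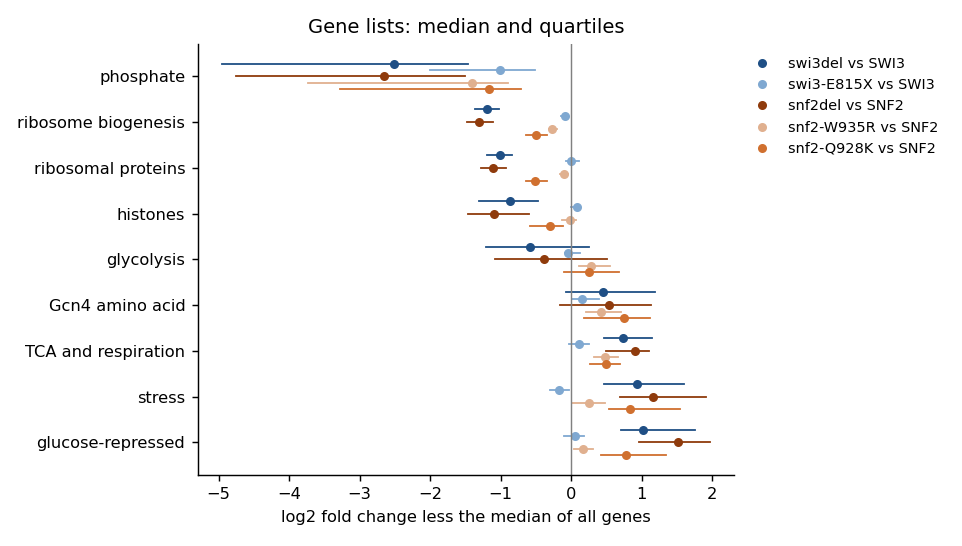
Median (point) and quartiles (line) of the log2 fold changes of 9 gene lists, less the median of all genes, in the 5 comparisons of a mutant with its own wild type. The phosphate list lies below 0 in all 5, at medians between -2.65 and -1.01, while the ribosomal protein list is at -0.01 in swi3-E815X and -1.12 in snf2del.

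How far the point alleles share the response to a deletion was measured on genes chosen in the deletion of the other family, which has its own control libraries. Of 1122 genes higher by 2-fold or more in swi3del, the median log2 change was 1.49 in snf2del, 0.70 (quartiles 0.39 and 1.12) in snf2-Q928K and 0.25 (0.06 and 0.47) in snf2-W935R; 848 and 423 of them were called higher in these alleles. Of 324 lower genes the medians were -1.38, -0.68 and -0.39, with 272 and 202 called lower. Of 1265 genes higher in snf2del the median was 0.11 (-0.03 and 0.28) in swi3-E815X, with 131 called higher, and of 398 lower genes it was -0.19 (-0.82 and -0.08), with 150 called lower. These medians depend on the choice of genes and on scaling. With no fold limit those of swi3-E815X were 0.0333 and -0.11 and those of snf2-W935R 0.13 and -0.14, and with median-ratio scaling those of swi3-E815X were 0.16 and -0.13. With genes chosen in the deletion of the same family the lower genes of swi3-E815X had -0.32. Of the genes higher by 2-fold, 1074 in snf2-W935R and 951 in snf2-Q928K were called lower than in snf2del, and 1198 in swi3-E815X lower than in swi3del.

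**Figure D5:**
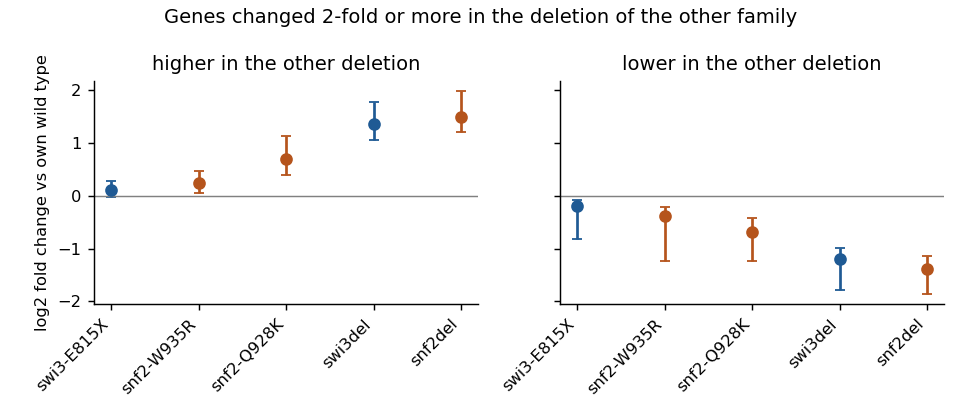
Median log2 fold change (point) with the quartiles (bars) of genes that were higher (left) or lower (right) by 2-fold or more in the deletion of the other family, in each mutant against its own wild type; the SWI3 family is blue and the SNF2 family orange. The medians run from 0.11 in swi3-E815X to 1.49 in snf2del on the left and from -0.19 to -1.38 on the right.

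Calls shared between alleles exceeded those of independent lists. Of the 196 higher and 369 lower genes of swi3-E815X, 144 and 259 went the same way in snf2-W935R, against 31.9 and 40.3 for independent lists. In snf2-Q928K 170 and 228 did, against 71.1 and 76.5. In snf2del 179 and 248 did, against 98.4 and 90.8, and 66 calls were opposite. The fold changes of swi3-E815X correlated with those of snf2-W935R at r = 0.612 and with those of snf2-Q928K at r = 0.477 across genes. Within a family the comparisons share control libraries. For snf2-W935R and snf2-Q928K r was 0.747 and the covariance 0.200, against 0.505 and 0.0107 in simulated unchanged groups. The pair shared 861 higher and 495 lower calls, against 378 and 145 for independent lists and none in the simulation. Unchanged groups have hardly any calls to share. The simulation therefore cannot tell how many calls changed groups share through a common control. For snf2-Q928K and snf2del r was 0.80 (simulated 0.504) and the covariance 0.473 (0.0105), and for snf2-W935R and snf2del they were 0.586 (0.497) and 0.244 (0.0107). For swi3-E815X and swi3del they were 0.536 (0.503) and 0.154 (0.0123). This r lies near that of unchanged groups, whose r comes from the shared control, so r alone cannot judge this pair. The pair shared 183 higher and 273 lower calls, against 92.8 and 89.7 for independent lists, and 60 calls were opposite. The 3 control libraries were too few to split, so part of the excess may come from the shared controls.

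Whether the effects of the alleles differ between the families was tested with both wild types in the contrast. For the deletions 55 genes had a higher effect in swi3del and 91 a lower one. Of these, 43 of the 55 lie in the chromosome IV stretch and 60 of the 91 near chromosome ends, and a fit without both regions called 5 and 14. With both deletions set against the SWI3 wild type 7 and 22 differed, SWI3 itself among them. A common control cancels from such a difference, so this fit compared the mutants directly. It has fewer groups in the contrast, and so a smaller error, and takes in any difference between the strains of the families. For the deletion effects 8 lists passed, with at most 5 members called in each: the interference (2 of 16 lower; adjusted p = 0.0202, and 0.531 with an estimated correlation), glucose-repressed, glycolytic, purine and stress lists lower in swi3del, and the ribosomal protein, ribosome biogenesis and iron lists higher. None passed with an estimated correlation, and 5 of the 8 (interference, glucose-repressed, glycolytic, purine and iron) also passed between the wild types. For swi3-E815X against snf2-W935R 147 effects were higher and 347 lower, 39 of the 147 in the stretch and 61 of the 347 near chromosome ends. The counts were 224 and 282 after median-ratio scaling, and 86 were higher without both regions. With the SWI3 wild type as the common control, which cancels here too, the counts were 424 and 791. Phosphate genes differed in 7 of 16 cases, falling less in swi3-E815X, with SPL2 at 2.61 ± 0.34, PHO89 at 2.32 ± 0.27 and PHM6 at 1.74 ± 0.33 (adjusted p of the list 5.42e-11; 0.130 with an estimated correlation), as did HO (1.83 ± 0.14). For swi3-E815X against snf2-Q928K 647 were higher and 1899 lower (1168 and 1362 after median-ratio scaling), led by HO (3.82 ± 0.14), YHB1 (3.37 ± 0.12), SPL2, PTR2 and PHM6 above and SER3 (-5.21 ± 0.10), ADH7, RDS1, SOL4 and HSP12 below. The low levels of ADH7 and RDS1 in the SNF2 wild type add to their differences.

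The authors' deposited tables of the 5 comparisons of a mutant with its wild type were set beside these fits. At an adjusted p below 0.05 the authors' deposited table listed 1028 genes higher and 1090 lower in swi3del, 51 and 60 in swi3-E815X, 1097 and 1105 in snf2del, 161 and 137 in snf2-W935R and 556 and 518 in snf2-Q928K. The authors' deposited table of snf2del holds only genes below that limit. Across shared genes the log2 fold changes of the authors' deposited tables correlated with those fitted here at r between 0.940 and 0.993, and no gene called in both had opposite directions. Of the calls in the authors' deposited tables on shared genes, 2010 of 2078 were also called here in swi3del, 102 of 110 in swi3-E815X, 2101 of 2162 in snf2del, 282 of 291 in snf2-W935R and 1034 of 1058 in snf2-Q928K. Most calls made here are not calls in the authors' deposited tables: on the shared genes 4312 were called here in swi3del, 458 in swi3-E815X, 1562 in snf2-W935R and 3430 in snf2-Q928K. What the p-values of the authors' deposited tables were computed from is not stated, but their mean signals lay on the scale of TPM. For SER3 in snf2-Q928K the mean signal was 488, beside mean levels of 31.6 TPM in SNF2 and 998 in snf2-Q928K. In swi3del it was 158, beside 37.9 TPM in SWI3 and 308 in swi3del. The input may thus have been TPM. Whether this accounts for the smaller number of calls was not tested.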

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

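The tests of an extra copy of the chromosome IV stretch, of lower expression of its genes in snf2 mutants, of higher expression near chromosome ends, of the dose of SIR4, and of SER3 were chosen after the results were seen, as were the fits with the SWI3 wild type as the common control and without both regions. The tests of scaling and of shared reads near the ends were written beforehand.

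Effects that differ between the families were singled out because the difference itself passed limma's test. Between the deletions 55 effects were higher in swi3del and 91 lower. SNU56 (1.35), COX20 (1.25), YAP6 (1.23), MNN10 (1.15) and RAD9 (1.15) led the first, and SWI3 (-4.67), the gene deleted in one family only, ADH7 (-3.72), RDS1 (-3.62), COS8 (-2.60) and AAD3 (-2.53) the second, as differences of log2 fold changes. With the SWI3 wild type as the common control, which cancels so that the mutants are compared directly, SWI3 kept its call. The other 9 lost theirs, at values between -0.30 (ADH7) and 0.33 (SNU56). Between swi3-E815X and snf2-W935R 147 were higher and 347 lower, led by SPL2 (2.61), PHO89 (2.32), HO (1.83), RDN5-1 (1.83) and PHM6 (1.74), and by RDS1 (-3.49), ADH7 (-3.11), AAD3 (-2.54), COS8 (-2.31) and COS10 (-1.62). With that control RDS1 (-0.01) and AAD3 (-0.01) lost the call, and ADH7 (0.30), COS8 (0.21) and COS10 (0.24) changed direction. Between swi3-E815X and snf2-Q928K 647 were higher and 1899 lower, led by HO (3.82), YHB1 (3.37), SPL2 (3.15), PTR2 (3.01) and PHM6 (2.41), and by SER3 (-5.21), ADH7 (-3.79), RDS1 (-3.56), SOL4 (-3.20) and HSP12 (-3.02). With that control RDS1 lost the call (-0.08). ADH7 is likewise low in the SNF2 wild type, which makes its difference larger in size.

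Spacers of the ribosomal DNA are in the authors' deposited tables and not in the table of levels, and were singled out as signals outside the comparisons made here. In the authors' deposited table of swi3del the log2 changes were 2.60 for NTS2-1, 2.65 for NTS2-2, 2.31 for NTS1-2, 1.59 for ETS1-2, 2.13 for ITS1-1, 1.58 for ETS1-1, 1.55 for ITS2-1, 2.02 for ITS1-2 and 0.93 for ITS2-2. In that of snf2del they were 1.92 for NTS2-1, 1.95 for NTS2-2, 1.80 for NTS1-2, 2.22 for ITS1-1, 1.58 for ETS1-2, 1.58 for ETS1-1, 2.19 for ITS1-2 and 1.92 for ITS2-1. In that of snf2-W935R NTS2-1 (-2.36), NTS2-2 (-2.56) and NTS1-2 (-1.94) were lower, and no other spacer had an adjusted p under 0.05. In the authors' deposited tables of snf2-Q928K and swi3-E815X no spacer did. These repeats share reads and were sequenced after poly(A) selection.

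Of the 48 genes of the chromosome IV stretch 47 were higher in the SNF2 wild type, and 43 of the 55 higher effects of swi3del lie there. Lower expression in the snf2 mutants is argued against by snf2-W935R, whose stretch lay at the level of the SWI3 wild type (median SWI3 minus snf2-W935R -0.0364). After median-ratio scaling the median over the stretch stayed at 0.92. That scaling divides each library by 1 factor and could not remove a difference of 1 stretch, so this outcome was fixed in advance. A factor per library would move all genes alike, and the 58 genes within 60 kb of the stretch had a median of -0.02. An extra copy in the SNF2 wild-type strain may be the source: the median of 0.92 is near the 1 of a second copy. All 29 windows of 20 genes inside lay between 0.89 and 0.96, and 5349 windows elsewhere, those with genes near chromosome ends left out, between -0.15 and 0.28. The stretch was chosen after its values were seen and its windows share genes, so the windows inside are no independent support. DNA of these strains was not used here, so an extra copy stays a hypothesis. The medians over the stretch were 0.92, 0.96 and 0.89 in the 3 SNF2 libraries and at most 0.23 in any other library.

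Genes near chromosome ends were lower in the SNF2 wild type, at a median of -0.57 within 10 kb and -0.04 at 20 to 40 kb. Reads shared between similar genes stay open: the 90 end genes with no similar copy had a median of -0.10 (-0.0973), which met the bound written beforehand for this explanation. A further condition was added after that value was seen, since 0% of 10000 random lists of the same size had a median as low. Of these 90 genes 13 were called lower, RDS1, ADH7 and COS10 among them, which this explanation does not predict for genes with no similar copy. Higher expression in snf2-W935R cannot be told apart from a low wild type (median 0.24 against SWI3 for the end genes called higher against SNF2). In snf2-Q928K that median was 0.67. Both sets of genes were chosen with the same mutant libraries that were then measured, which can raise these medians. Over all end genes, without that choice, the medians against SWI3 were 0.08 in snf2-W935R and 0.48 in snf2-Q928K, beside 0.83 in snf2del and 0.82 in swi3del. The dose of SIR4, a silencing gene in the chromosome IV stretch at 38.5 ± 3.58 TPM in SNF2 and 19.2 ± 0.922 in SWI3, may lower genes near ends (-0.53 within 10 kb less that at 20 to 40 kb), but 1 strain carries both differences, so it stays open.

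SER3 rose more in snf2-Q928K than in snf2del. Reads shared with the paralog SER33 are argued against by the size of its change, 51.2 TPM beside 966 for SER3. A general rise of amino acid genes stays open as a part of the rise. The Gcn4 list had a median of 0.85, and most of its members rose. SER3 was the largest rise of the comparison, so a list median below it was fixed in advance and cannot decide this. Loss of SRG1 RNA, whose transcription is known to repress SER3, stays open: SRG1 changed by 0.39 on the log2 scale, not downward, but SER3 reads in the 77 shared bases could add up to 139.5 TPM to it. The RNA also does not measure whether transcription of SRG1 still reaches the SER3 promoter.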

How the results depend on the processing

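The fits with the SWI3 wild type in place of SNF2, and those without the chromosome IV stretch and the chromosome ends, were chosen after seeing the data; the other alternatives were planned. Of 436 alternatives for counts of called genes 410 stayed within 1.5 times, as did 393 of 436 for counts of 2-fold genes. Of 10961 for named genes 10694 kept their side of the threshold, 218 lost and 41 gained a call, and 8 changed sign with a call in at least 1 of the fits. Where no cause is named, the cause was not tested.

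Scaling recentres the median of all genes, and it moved counts. With median-ratio scaling the higher genes of swi3-E815X against swi3del went from 1335 to 2180, the lower of snf2del from 1574 to 2414, the higher of snf2-W935R against snf2del from 1500 to 2382 and the lower of snf2-Q928K against snf2-W935R from 900 to 1396. Higher effects went from 147 to 224 (swi3-E815X against snf2-W935R) and from 647 to 1168 (against snf2-Q928K). With quantile normalization the lower genes of swi3del went from 1554 to 2412, swi3-E815X against swi3del to 2325 and 1985 (from 3071 lower), the lower of snf2del to 2593, the higher of snf2-W935R and snf2-Q928K against snf2del to 2559 and 2195 (from 1424), the lower of snf2-Q928K against snf2-W935R to 1494, and swi3-E815X against snf2-Q928K effects to 1187 and 1216 (from 1899 lower); MF(ALPHA)2 in snf2del reversed to -0.63.

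With the SWI3 wild type as the control the deletion effects went from 55 and 91 to 7 and 22, and those of swi3-E815X against snf2-W935R from 147 and 347 to 424 and 791. That control cancels from a difference of effects, so the mutants were compared directly. Such a contrast has fewer groups and a smaller error, so the counts differ in precision too. Reversed were ADH7 (-0.0124), COS8 (-0.0059) and HTB1 (0.28) in snf2-W935R, SWI3 in snf2-Q928K (0.18), and ADH7 (0.30), COS8 (0.21) and COS10 (0.24) between swi3-E815X and snf2-W935R. Without both regions, which removes genes, the deletion effects were 5 and 14, the higher effects of swi3-E815X against snf2-W935R 86, and the wild types 21 and 40 (from 90 and 164). Leaving out single libraries moved the lower genes of SNF2 against SWI3 to between 95 and 185.

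Of all 27 lists tested, those past the threshold numbered 12 (swi3del), 14 (swi3-E815X), 12 (swi3-E815X against swi3del), 12 (snf2del), 16 (snf2-W935R), 11 (snf2-Q928K), 12 and 13 (snf2-W935R and snf2-Q928K against snf2del), 11 (snf2-Q928K against snf2-W935R), 8, 10 and 11 (effects) and 8 (wild types). With an estimated correlation there was 1 in swi3-E815X and 0 in every other comparison. With fry, which compares no list with other genes, they were 26 in swi3del, 24 in swi3-E815X against swi3del, 24 in snf2del, 25 in snf2-Q928K, 24 and 24 for snf2-W935R and snf2-Q928K against snf2del, 19 for snf2-Q928K against snf2-W935R, 5 for the deletion effects, 21 for swi3-E815X against snf2-Q928K effects and 4 for the wild types.

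The medians of deletion-responsive genes kept their direction. For higher genes in swi3-E815X the median went from 0.11 to 0.14 with genes called in the same family, 0.0333 with no fold limit and 0.16 with median-ratio scaling, and to between 0.0857 and 0.135 without single libraries. For lower genes it went from -0.19 to -0.32, -0.11 and -0.13 in these settings. In snf2-W935R higher genes went from 0.25 to 0.13 with no fold limit, and lower genes from -0.39 to -0.34 (same family), -0.14 (no fold limit), -0.29 (median-ratio scaling) and between -0.42 and -0.37 without single libraries. In snf2-Q928K higher genes went from 0.70 to 0.74 (same family), 0.40 (no fold limit), 0.73 (pseudocount 0.1), 0.73 (median-ratio scaling) and 0.68 (without both regions), and lower genes from -0.68 to -0.28 (no fold limit).

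Deviations of libraries with the same replicate number had correlations between -0.0129 and 0.188 in the SWI3 family (median 0.0564, against -0.0225 for different numbers) and between -0.185 and 0.167 in the SNF2 family (-0.0138 against 0.0128). With the replicate number as a block (replicate block) calls numbered 3049 and 1578 in swi3del, 231 and 367 in swi3-E815X, 3179 and 1558 in snf2del, 983 and 665 in snf2-W935R and 2291 and 1294 in snf2-Q928K, all within 1.5 times. In camera the block took the zinc (adjusted p = 0.0627) and hypoxic (0.0626) lists of swi3-E815X past 0.05, and the list of genes known to need Swi/Snf in swi3-E815X against swi3del (0.051), and brought the strain markers of snf2del under it (0.0461). DESeq2 was planned for counts and was not run, since TPM keeps no depth.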

Other observations

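The tests on Ty genes were chosen after the results were seen; the counts of other splits of the libraries were planned. Genes of Ty elements, retrotransposons present in many similar copies whose reads are shared, were lower in all 5 mutants. Summed over Ty genes, levels were 6617 ± 122 TPM in SWI3, 3020 ± 67.8 in swi3-E815X and 1654 ± 46.2 in swi3del, and 5848 ± 689 in SNF2, 2346 ± 44.7 in snf2-W935R, 2546 ± 245 in snf2-Q928K and 1680 ± 184 in snf2del (SD, n = 3). Of 89 Ty genes 83 fell in swi3del and 83 in swi3-E815X, at medians of -1.90 and -1.10, and of 88 in the SNF2 family 80 fell in snf2del, 77 in snf2-W935R and 75 in snf2-Q928K, at -1.72, -1.04 and -0.99. None of 90 was called by limma between the wild types (0 higher and 0 lower; median -0.17).

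The sulfur gene MET3 was higher in each allele than in the deletion of its family, by log2 differences of 0.62 ± 0.09 in swi3-E815X, 0.58 ± 0.07 in snf2-W935R and 0.79 ± 0.07 in snf2-Q928K (SE; limma adjusted p = 5.13e-05 or less). It stood at 37.2 TPM in SWI3, 132 in swi3-E815X and 85.6 in swi3del, and at 59.5 in SNF2, 119 in snf2-W935R, 138 in snf2-Q928K and 79.4 in snf2del. ARG3 was higher by 0.41 ± 0.15, 1.66 ± 0.31 and 1.91 ± 0.31 (adjusted p = 0.026 or less), at 19.7, 88.0 and 65.6 TPM in the SWI3 family and 22.8, 179, 213 and 56.0 in the SNF2 family. BSC1 was lower than in the deletion in swi3-E815X (-0.96 ± 0.17, adjusted p = 3.45e-04) and snf2-W935R (-0.98 ± 0.14, 1.64e-05), at 3.30 and 3.04 TPM, with 7.23 in swi3del and 6.95 in snf2del.

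A candidate explanation for the Ty genes is that their transcripts need Swi/Snf. The weaker of the median changes in the deletions was -1.72 (all genes 0.26), as this needs, in data that also gave rise to the idea. Since the copies share reads, a change at few elements could appear at many.

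Splits of the libraries were counted for each comparison of 3 libraries with 3. Each has 10 splits, too few for a share under 0.05, and 1 of the 10 (the real one) gave as many calls in each of the 13 comparisons. Every other split mixes libraries of both groups, so a real difference adds to the spread within groups and few calls remain. The low counts of the other splits were thus largely fixed in advance and do not argue against a grouping by chance. The real number and the highest of the other splits were 4583 and 0 for swi3del, 565 and 0 for swi3-E815X, 4406 and 0 for swi3-E815X against swi3del, 4786 and 0 for snf2del, 1739 and 0 for snf2-W935R and 3646 and 0 for snf2-Q928K. Against snf2del they were 4605 and 0 for snf2-W935R and 4016 and 2 for snf2-Q928K, and between these alleles 2818 and 0. For differences of effects, counted after removing the wild-type difference, they were 151 and 0 for the deletions, 497 and 0 for swi3-E815X and snf2-W935R and 2549 and 1 for swi3-E815X and snf2-Q928K, and for the wild types 254 and 1.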
